A study of Mus musculus with 9 samples.

How the data were processed

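RNA sequencing was available for 9 mouse libraries in 3 groups of 3. Primary neural crest cells (pNCC) came from embryos at day 13.5. Corneal endothelial-like cells (iCEC) were induced from neural crest cells in a medium with 5% knockout serum replacement (KSR) and 5 µM SB431542, an inhibitor of the TGF-β type I receptor. Per the labels this medium was renewed every 2 days, clusters appeared by day 4 and colonies were characterised on day 12. Primary corneal endothelial cells (pCEC) and pNCC were kept in a medium with 10% fetal bovine serum. The labels give paired reads of 150 bases and name polyA RNA as the molecule, except for pCEC replicates 2 and 3, which they label total RNA. Groups and replicate numbers were taken from the sample titles. The labels do not say whether replicates came from separate animals. Sex-linked transcripts differed between libraries of iCEC and of pCEC, so those replicates were not all drawn from the same sample, while the replicates of pNCC may be technical. The p values measure only the spread between these libraries.

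The deposited table holds raw counts per gene symbol, whole numbers with no normalization, for 56481 symbols. Of these, 31906 had a count in any library. Per the labels the genome build was mm10 and edgeR was used. The role of edgeR, its version, the aligner, the counting tool and the gene annotation were not given. Symbols were matched to GENCODE release M21 for positions, and 48988 of them (86.7%) matched 1 gene. Of the 307 genes eligible to be named, 305 matched.

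Each comparison was fitted on the 6 libraries of its own 2 groups in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr, libraries were scaled by TMM, and a robust quasi-likelihood fit with group as the only term was tested 2-sided. Adjusted p values are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05. Counts scaled to library size (CPM) are given as the mean ± SD over 3 libraries, and SE is an approximate standard error of a log2 fold change. It was computed as the absolute log2 fold change divided by the square root of the F statistic, so it restates that test. Where all 3 libraries of a group had a count of 0, the fold is a lower bound computed at 3 counts in each library. Where a group had 1 to 3 counts, the fold is a ratio of summed counts with its 95% counting interval. Such intervals and bounds cover counting error only. Total counts ran from 27389292 to 47967113, so that 3 counts amounted to 0.0616 to 0.126 CPM.

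Lists of 34 kinds of genes (pathways, structures and markers of cell types) were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2. The inter-gene correlation was preset at 0.01, and lists with at least 5 tested members were adjusted together by Benjamini-Hochberg. Camera with an estimated correlation and fry were run beside it. The tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule took the 10 genes with the largest change in each direction, among called genes with non-overlapping groups and a mean of at least 10 CPM. Chance alone gives non-overlapping groups in 10% of genes for 3 against 3. It also took up to 4 called members per list with the smallest adjusted p, all members of the corneal endothelium, neural crest and TGF-β response lists, and markers of other cell types.

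The genes changed against pNCC in both iCEC and pCEC were counted by direction. The same 3 pNCC libraries serve both comparisons and could not be divided, so 20 data sets with no group difference were simulated against shared controls. Distances were Euclidean on log2 CPM of the 17616 genes past the filter over all 9 libraries, divided by the square root of the number of genes. With 3 against 3 libraries an exact permutation test cannot go below p = 0.1, so distances carry no test.

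Alternatives were DESeq2 size factors in edgeR, the DESeq2 1.42.0 Wald test, no filter on low counts, a filter of 1 CPM in 3 libraries, all 9 libraries in one fit, replicate number as a block, each library left out in turn, pCEC represented by the library labelled polyA RNA alone, and a minimum of 2-fold. Where pCEC was 1 library, it was assumed to vary like the other group. A filter of 1 CPM in every library was added after seeing the data. A planned change of pseudocount applied to normalized values only and was not used for counts. Further work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

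The fit was tested on simulated data with 200 changed genes, drawn with the dispersions of each comparison. In a first design with 2- and 4-fold changes, edgeR recovered 0% of both sizes in iCEC vs pNCC, 35.7% and 70.4% in pCEC vs pNCC, and 1.05% and 19.15% in iCEC vs pCEC, although the median fitted log2 fold changes of iCEC vs pNCC were 0.95 and 1.91. A second design, added after that result, spread the 200 genes over 2-, 4-, 16- and 64-fold. It recovered 2.13%, 45.8%, 70.8% and 90.0% in iCEC vs pNCC, 40.0%, 64.0%, 96.0% and 100% in pCEC vs pNCC, and 0%, 35.4%, 67.35% and 82.0% in iCEC vs pCEC. Recovery of a given fold differed between the designs, and the cause was not tested. The simulations changed 200 genes, whereas edgeR called 5093 of 16293 in the data of iCEC vs pNCC. A Benjamini-Hochberg threshold is stricter where fewer genes change, so these shares do not measure recovery in the data. In iCEC vs pNCC the 4-fold genes of the first design had a median unadjusted p of 0.00133 by edgeR. Of the unchanged genes, at most 0.0749% were called in either design.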

Results

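Transcript counts were compared between 3 kinds of mouse cells, with 3 libraries each. These were primary neural crest cells from embryos (pNCC), cells induced from neural crest cells by the TGF-β type I receptor inhibitor SB431542 (iCEC), and cells labelled primary corneal endothelial cells (pCEC). The corneal endothelium is the cell layer on the inner face of the cornea, which pumps ions and water out of the stroma and derives in large part from the neural crest. Total counts ran from 27389292 in pCEC 3 to 47967113 in iCEC 1. The comparisons ask how iCEC and the libraries labelled pCEC each differed from pNCC, and how far iCEC resembled the libraries labelled pCEC.

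The 3 groups lay apart from each other. The first principal component of log2 CPM held 56.1% of the variance and separated pNCC from the other groups, and the second, with 25.7%, separated iCEC from pCEC. The mean distance per gene was 2.58 between iCEC and pNCC, 2.75 between pCEC and pNCC, and 2.18 between iCEC and pCEC. Within groups it was 0.679 in pNCC, 1.57 in iCEC and 0.871 in pCEC. Each iCEC library lay nearer to the pCEC libraries than to the pNCC libraries, with ratios of the 2 distances of 0.828 in iCEC 1, 0.803 in iCEC 2 and 0.910 in iCEC 3 (mean 0.847 ± 0.056, SD, n = 3). iCEC 3 stood at 1.73 and 1.80 from iCEC 1 and iCEC 2, which were 1.17 apart.

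**Figure D1:**
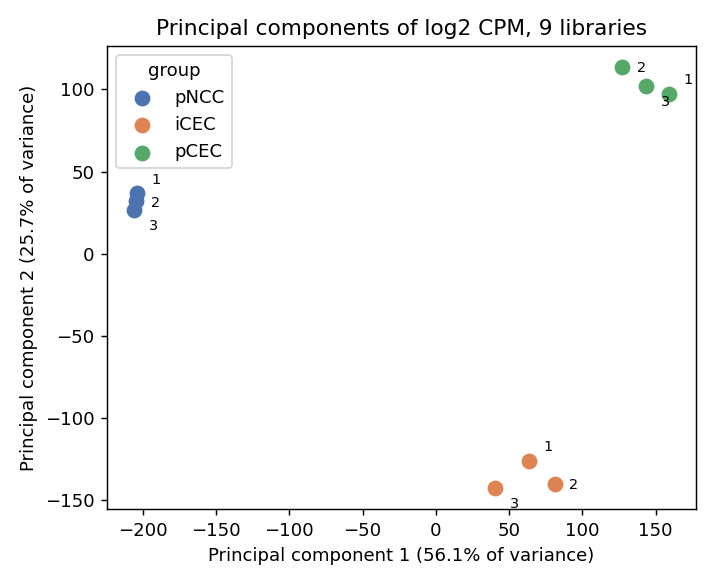
Principal components 1 and 2 of log2 CPM over 9 libraries, in arbitrary units, with the share of variance on each axis. Each point is a library, coloured by group and marked with its replicate number; the 3 groups formed separate clusters, and component 1 held 56.1% of the variance.

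In iCEC, genes of surface epithelia were far higher than in pNCC. The keratin Krt5 (chromosome 15, 101707070 to 101712898, minus strand, mm10) stood at 6124 ± 3036 CPM (SD, n = 3) in iCEC and 41.5 ± 12.5 CPM in pNCC, a 148-fold difference. Its partner Krt14 was 136-fold higher, E-cadherin (Cdh1) 191-fold, the epithelial splicing factor Esrp1 244-fold and Trp63, a transcription factor of stratified epithelia, 185-fold. All 13 tested members of the surface epithelium list were higher in iCEC, also when adjusted over the list alone, with a median log2 fold change of 7.96 (camera adjusted p = 3.17e-12). This was the only list that passed with an estimated correlation (adjusted p = 0.0422 with an estimated correlation). The corneal keratin Krt12 and the eye field factor Pax6 were not among the 13 tested members, at a mean of 0.00829 and 0.300 CPM in iCEC.

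Members of the corneal endothelium list went both ways in iCEC relative to pNCC. Of 20 members, 6 were higher, 3 were lower and 11 did not pass, with the same counts adjusted over the list alone. The ion pump subunit Atp1b1 was 16.8-fold higher, carbonic anhydrase Car2 56.2-fold (53.7 ± 46.0 CPM against 0.956 ± 0.672 CPM) and the transcription factor Foxc1 24.2-fold (176 ± 84.5 CPM against 7.28 ± 3.97 CPM). The borate and proton transporter Slc4a11 was 3.77-fold higher (6.46 ± 3.55 CPM against 1.72 ± 0.464 CPM, adjusted p = 0.0323) and the junction protein Tjp1 2.67-fold. The collagen Col8a2 of Descemet's membrane (chromosome 4, 126286793 to 126314330, plus strand, mm10) fell 149-fold, to 0.0714 ± 0.0623 CPM from 10.6 ± 6.50 CPM. The water channel Aqp1 fell 344-fold and N-cadherin (Cdh2) 565-fold. The list as a whole did not pass, with a median log2 fold change of 0.53, a mean of -0.15 and an upward camera test (adjusted p = 0.931). The log2 fold change of Car2 was 5.84, against 4.88 without iCEC 1 and 6.44 without pNCC 2. Without iCEC 1 it was -6.56 for Col8a2 (-7.18 with all libraries) and -9.50 for Aqp1 (-8.33). The call of Slc4a11 was lost without pNCC 1 (adjusted p = 0.1), pNCC 2 (0.139), pNCC 3 (0.107) or iCEC 1 (0.0678). The call of Tjp1 was lost without pNCC 1 (adjusted p = 0.0871), pNCC 2 (0.0855), pNCC 3 (0.0939), iCEC 1 (0.0586) or iCEC 2 (0.0586).

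Neural crest and mesenchymal genes were lower in iCEC. Of 19 tested neural crest members, 10 were lower and 3 higher (11 and 4 adjusted over the list alone), with adjusted p = 0.0188 by camera and adjusted p = 0.344 with an estimated correlation. The mesenchymal factor Prrx1 fell 80.8-fold, and the crest specifier Foxd3, at 0 in every iCEC library, was at least 251-fold lower. Sox10, with 1 to 3 counts in iCEC, was 2127-fold lower (95% counting interval 589 to 17570), and its counts there were all in iCEC 2. Sox9, Tfap2a and Msx2, which are also active in epithelia, were higher. Of 18 members of the fibrillar matrix list 15 were lower and none higher (17 lower adjusted over the list alone, camera adjusted p = 1.23e-10, adjusted p = 0.199 with an estimated correlation), among them Bgn, Lox and Sparc at 16720-, 170- and 31.7-fold. Of 16 contractile and mesenchymal transition genes 11 were lower (12 adjusted over the list alone, adjusted p = 3.06e-05, adjusted p = 0.199 with an estimated correlation), with Vim 58.1-fold, Zeb1 56.2-fold and Acta2 10.2-fold lower. Of 21 genes known to rise with TGF-β signalling 7 were lower, 1 was higher and 13 did not pass (8 and 1 adjusted over the list alone, adjusted p = 0.0111, adjusted p = 0.246 with an estimated correlation). Among them, Tgfbi, an extracellular matrix protein, did not pass and stood at 91.0 ± 46.6 CPM against 304 ± 125 CPM (adjusted p = 0.0542). Without iCEC 1 the log2 fold change was -16.03 for Bgn (-13.93 with all libraries) and -6.86 for Zeb1 (-5.77). The call of Msx2 was lost without pNCC 1 (adjusted p = 0.0963), pNCC 2 (0.0826), pNCC 3 (0.0952) or iCEC 1 (0.0528).

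Junction genes were mostly higher in iCEC. Of 21 tested junction genes 16 were higher and 3 lower, also adjusted over the list alone (camera adjusted p = 4.15e-05, adjusted p = 0.199 with an estimated correlation). Of 16 ion and fluid transport genes 7 were higher and 2 lower, also adjusted over the list alone (adjusted p = 0.0491, adjusted p = 0.267 with an estimated correlation). This list call was lost without pNCC 1 (adjusted p = 0.0709), pNCC 3 (0.0512), iCEC 1 (0.0533) or iCEC 2 (0.0569). The respiratory chain list had 10 of 22 members higher (12 adjusted over the list alone, adjusted p = 0.00122, adjusted p = 0.472 with an estimated correlation). The cytosolic ribosomal list had 10 of 29 higher (12 adjusted over the list alone, adjusted p = 0.000249, adjusted p = 0.604 with an estimated correlation). Of 29 cell cycle genes 5 were lower (4 adjusted over the list alone, adjusted p = 0.000106, adjusted p = 0.604 with an estimated correlation), including Mcm2 and Mcm6 of the replicative helicase at 2.67- and 2.41-fold. Markers of skeletal muscle were lower for 10 of 12 members, also adjusted over the list alone (adjusted p = 1.36e-05, adjusted p = 0.337 with an estimated correlation), keratocyte markers for 5 of 10 with 1 higher (6 and 1 adjusted over the list alone, adjusted p = 0.0036, adjusted p = 0.199 with an estimated correlation), and vessel endothelium markers for 4 of 10 (6 adjusted over the list alone, adjusted p = 0.0111, adjusted p = 0.199 with an estimated correlation). The summed CPM of the vessel list was 9.05, 54.7 and 26.3 in iCEC 1, 2 and 3 and 46.7, 47.1 and 69.3 in pNCC 1, 2 and 3, so that iCEC 2 lay within the pNCC range. Interferon-stimulated genes were lower for 2 of 15 (1 adjusted over the list alone, adjusted p = 0.0165, adjusted p = 0.691 with an estimated correlation). Their summed CPM was 608, 1360.3 and 70.6 in iCEC 1, 2 and 3 and 1699.9, 1077 and 1387 in pNCC 1, 2 and 3, which again placed iCEC 2 within the pNCC range.

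Of 16293 genes tested between iCEC and pNCC, edgeR called 5093, of which 2630 were higher and 2463 lower in iCEC, and camera called 14 of 30 lists. When these libraries were divided 3 against 3 in all 10 ways, 4 of them, the real one included, called at least 14 lists (highest other 18). The number of lists thus does not set the real groups apart from mixed ones. The largest rises were in genes at 0 in every pNCC library, among them Sftpd and Tmprss4, at least 1547- and 890-fold higher. The largest falls included Mfap4, Tspan11 and Ccl11, at 0 in every iCEC library and at least 5145-, 1272- and 1239-fold lower. The gene count was 2523, 2322 and 2698 without pNCC 1, pNCC 2 and pNCC 3, and 7684 without iCEC 3. Of the 149 called genes eligible to be named, 46 lost the threshold without at least 1 library, and none changed direction.

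The libraries labelled pCEC held genes of the corneal surface epithelium at high levels. The corneal keratin Krt12 (chromosome 11, 99415666 to 99422259, minus strand, mm10) reached 11095 ± 1942 CPM and was at 0 in every pNCC library, at least 128400-fold higher. Krt5 stood at 29934 ± 7164 CPM, 721-fold above pNCC, and Pax6 was 8429-fold higher at 896 ± 73.5 CPM. Aldh3a1, an abundant dehydrogenase of the mouse cornea that is not a member of the surface epithelium list, reached 26743 ± 4104 CPM. Of 15 surface epithelium members 13 were higher and 2 did not pass, also adjusted over the list alone (camera adjusted p = 3.08e-07, adjusted p = 0.398 with an estimated correlation). The simple epithelial keratins Krt8 and Krt18 were the 2 that did not pass, at 4.19 ± 1.75 and 1.82 ± 0.631 CPM. The largest rises also held the mucins Muc4 and Muc21, at least 27590- and 12320-fold higher.

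Several corneal endothelium markers were higher in the same libraries. Of 20 members 9 were higher, 6 lower and 5 did not pass, also adjusted over the list alone. Col8a2 was 9.06-fold higher (96.3 ± 64.7 CPM against 10.6 ± 6.50 CPM), Slc4a11 38.0-fold, Lmx1b 20.7-fold, Foxc1 21.9-fold and the adhesion protein Alcam 10.4-fold. Cdh2 was 64.5-fold lower, the adhesion protein Ncam1 19.8-fold and the lactate carrier Slc16a1 10.3-fold. The list as a whole did not pass (median log2 fold change 0.79, camera adjusted p = 0.759). The keratocyte list also went both ways, with 4 of 12 members higher and 5 lower, also adjusted over the list alone. Its median log2 fold change was -0.89, its mean 0.73 and its camera test downward (adjusted p = 0.759). Kera, a proteoglycan of the corneal stroma, was 509-fold higher (328 ± 241 CPM), and Pdgfra and Thy1, markers of fibroblasts, were 36.5- and 1665-fold lower. Without pCEC 2 the log2 fold change was 2.52 for Col8a2 (3.15 with all libraries), -7.04 for Cdh2 (-5.997) and -5.01 for Ncam1 (-4.34), and without pNCC 1 it was 10.25 for Kera (8.95). Aqp1 was 2.91-fold higher (adjusted p = 0.0395), a call lost without pNCC 2 (adjusted p = 0.0818), pNCC 3 (0.0602), pCEC 2 (0.11) or pCEC 3 (0.101), and its log2 fold change ran from 0.39 to 1.90 over all alternatives.

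Neural crest, matrix and contractile genes were lower in pCEC than in pNCC. Of 19 crest members 14 were lower and 2 higher, also adjusted over the list alone (camera adjusted p = 0.00307, adjusted p = 0.866 with an estimated correlation), with Sox10 104-fold and Foxd3 160-fold lower. Without pCEC 1 the log2 fold change of Sox10 was -6.09 (-6.77 with all libraries). Contractile genes were lower for 15 of 16 members, also adjusted over the list alone (adjusted p = 3.2e-06, adjusted p = 0.811 with an estimated correlation), and Acta2 fell 823-fold. Fibrillar matrix genes were lower for 16 of 18 (17 adjusted over the list alone, adjusted p = 4.26e-05, adjusted p = 0.866 with an estimated correlation). Of 21 TGF-β response genes 15 were lower and 4 higher, also adjusted over the list alone (adjusted p = 0.00341, adjusted p = 0.866 with an estimated correlation). Postn, a matricellular protein, was 891-fold lower, while Tgfbi, an abundant protein of the cornea, was 6.56-fold higher. Skeletal muscle markers were lower for 12 of 12, also adjusted over the list alone (adjusted p = 0.000499, adjusted p = 0.866 with an estimated correlation).

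Metabolic and proliferation genes also differed. Of 22 cholesterol synthesis genes 16 were higher in pCEC (18 adjusted over the list alone, camera adjusted p = 0.000542, adjusted p = 0.866 with an estimated correlation), with Hmgcs1, a synthase at the start of the pathway, 4.96-fold higher. Of 14 glycolysis genes 12 were lower (13 adjusted over the list alone, adjusted p = 0.00114, adjusted p = 0.866 with an estimated correlation), with Pgk1 4.496-fold and Gapdh 2.98-fold lower. Of 29 cell cycle genes 20 were lower, also adjusted over the list alone (adjusted p = 0.00034, adjusted p = 0.866 with an estimated correlation), with the mitotic factors Tpx2 and Kif20a 3.59- and 3.39-fold lower. Of 21 junction genes 15 were higher and 5 lower, also adjusted over the list alone (adjusted p = 0.00244, adjusted p = 0.487 with an estimated correlation), with the claudin Cldn4 129-fold higher.

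Of 16608 genes tested between pCEC and pNCC, edgeR called 10382, of which 5032 were higher and 5350 lower in pCEC, and camera called 10 of 31 lists. Of the 10 ways to divide these libraries 3 against 3, 5, the real one included, called at least 10 lists (highest other 15). Here too the number of lists does not set the real groups apart. The gene count lay between 9207 and 10687 when any 1 library was left out. Among the 191 called genes eligible to be named, 11 lost the threshold without at least 1 library. With pCEC represented by the library labelled polyA RNA alone, where the spread came from pNCC only, edgeR called 9288 genes. Of the 10382 calls 80.3% passed there in the same direction and 7 had the opposite sign, which says nothing about the spread of pCEC.

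**Figure D2:**
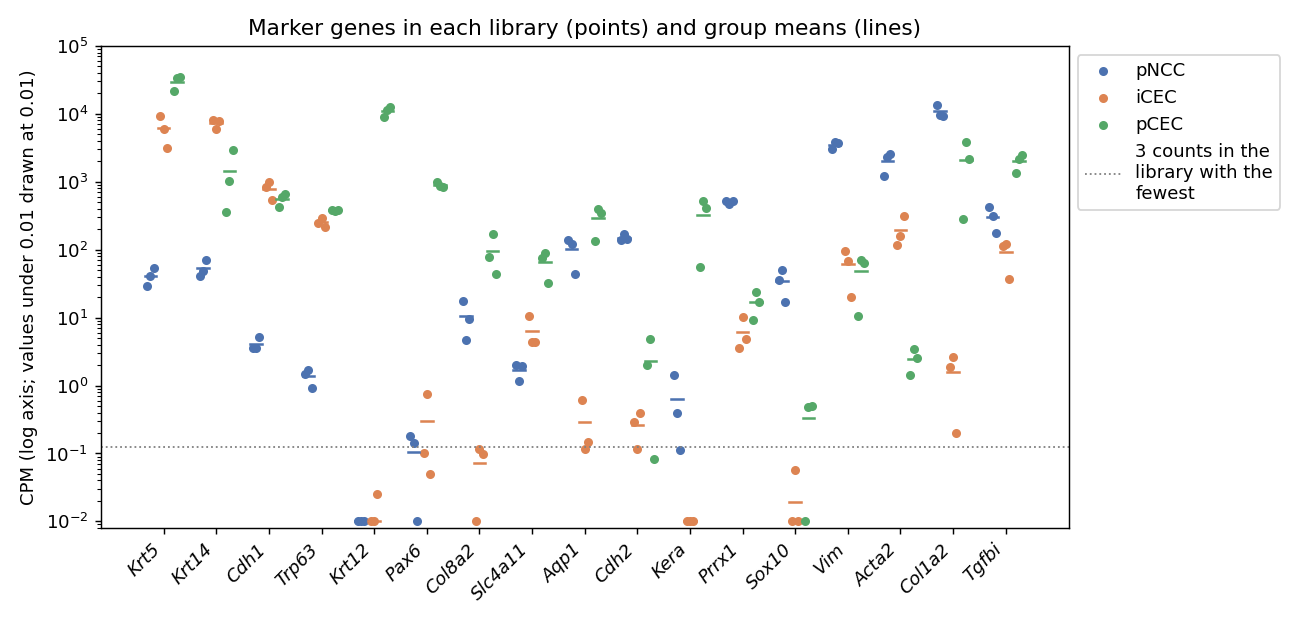
CPM of marker genes on a log axis, with 1 point per library, a line at each group mean and values under 0.01 drawn at 0.01; the dotted line marks 3 counts in the library with the fewest counts. Krt12 stood at a mean of 11095 CPM in pCEC and 0.00829 CPM in iCEC, and Col8a2 at 96.3 CPM in pCEC and 0.0714 CPM in iCEC.

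The libraries of iCEC and pCEC differed in corneal and keratin genes. Krt12 had 1 to 3 counts in iCEC and was 1350000-fold lower there than in pCEC (95% counting interval 242300 to 53320000), with its counts there all in iCEC 3. Pax6 was 2990-fold lower, with a log2 fold change of -11.55 that was -13.33 without iCEC 2. Krt8 and Krt18, keratins of simple epithelia, were 287- and 359-fold higher in iCEC, at 1200 ± 929 and 651 ± 449 CPM. Their log2 fold changes of 8.26 and 8.58 were 7.37 and 7.82 without iCEC 3. Of 15 surface epithelium genes 3 were higher in iCEC, 5 lower and 7 did not pass (5 higher and 6 lower adjusted over the list alone), and the list did not pass by camera (adjusted p = 0.528). Fry, in contrast, called the list lower in iCEC (fry adjusted p = 0.00277). Krt14, Trp63 and Cdh1 did not pass, with log2 fold changes of 2.42 ± 0.742, -0.54 ± 0.174 and 0.54 ± 0.293 (SE, n = 3 against 3).

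Corneal endothelium markers were divided between iCEC and pCEC. Of 20 members 4 were higher in iCEC, 3 lower and 13 did not pass (5 and 4 adjusted over the list alone). Col8a2 was 1347-fold lower in iCEC, Aqp1 1002-fold and Slc4a11 10.1-fold. Car2 was 110-fold higher and the proteoglycan Gpc4 4.71-fold higher. Without iCEC 1 the log2 fold change was -9.69 for Col8a2 (-10.36 with all libraries), -10.99 for Aqp1 (-9.84) and 5.85 for Car2 (6.79), and without pCEC 2 it was -9.68 for Col8a2 and 7.60 for Car2. Foxc1 stood at 176 ± 84.5 CPM in iCEC and 159 ± 29.8 CPM in pCEC (log2 fold change 0.22 ± 0.423, SE, adjusted p = 0.749). The list did not pass, with a median log2 fold change of 0.40, a mean of -0.39 and a downward camera test (adjusted p = 0.885). Of 15 ion and fluid transport genes 6 were higher in iCEC and 2 lower (8 and 2 adjusted over the list alone, adjusted p = 0.0365, adjusted p = 0.631 with an estimated correlation), a list call lost without iCEC 2 (adjusted p = 0.058) or iCEC 3 (0.0693).

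Stromal markers were lower in iCEC than in pCEC, and leukocyte markers went both ways. Of 12 keratocyte markers 6 were lower and none higher, also adjusted over the list alone (camera adjusted p = 3.66e-05, adjusted p = 0.631 with an estimated correlation). Kera, at 0 in every iCEC library, was at least 4426-fold lower, and Lum, a proteoglycan of collagen fibrils, was 3149-fold lower. Of 13 macrophage markers 6 were lower and 1 higher, also adjusted over the list alone (adjusted p = 0.00227, adjusted p = 0.631 with an estimated correlation). The leukocyte factor Spi1 and the complement gene C1qb stood at 3.26 ± 1.07 and 3.08 ± 1.65 CPM in pCEC and at 0 in every iCEC library. The higher member, the lipopolysaccharide receptor Cd14, stood at 309 ± 247 CPM in iCEC and 4.76 ± 0.789 CPM in pCEC. Its edgeR call was lost without pCEC 1 (adjusted p = 0.0529) or pCEC 2 (0.0525). The summed CPM of the list ran against the test in iCEC 1 and iCEC 2 and lay within the pCEC range in iCEC 3, at 392, 587 and 55.2 in iCEC 1, 2 and 3 and 33.7, 68.0 and 69.4 in pCEC 1, 2 and 3. The fibrillar matrix list had 5 of 18 members lower and 2 higher (6 and 2 adjusted over the list alone, adjusted p = 0.0275, adjusted p = 0.659 with an estimated correlation), with Col1a2 1355-fold lower and Tnc 149-fold higher in iCEC. The log2 fold change of Col1a2 was -9.59 without pCEC 2 (-10.37 with all libraries) and that of Tnc 8.60 without pCEC 3 (7.30). The summed CPM of the fibrillar matrix list was 1231 in pCEC 1, within the 869 to 1807 of the iCEC libraries, and 14212 and 8145 in pCEC 2 and pCEC 3, the 2 libraries labelled total RNA. The fibrillar matrix call was lost without pCEC 2 (adjusted p = 0.0528) or pCEC 3 (0.0604). Contractile genes were higher for 5 of 13 members, also adjusted over the list alone (adjusted p = 0.0266, adjusted p = 0.631 with an estimated correlation), with Acta2 80.4-fold and Tpm1 42.4-fold higher.

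Glycolysis and cholesterol synthesis genes differed between iCEC and pCEC. Of 14 glycolysis genes 12 were higher in iCEC, also adjusted over the list alone (camera adjusted p = 8.54e-07, adjusted p = 0.631 with an estimated correlation), with Pgk1 6.65-fold higher. Of 22 cholesterol synthesis genes 9 were lower (9 lower and 1 higher adjusted over the list alone, adjusted p = 3.66e-05, adjusted p = 0.631 with an estimated correlation), with Lss 3.37-fold lower. Respiratory chain genes were higher for 7 of 22 members (9 adjusted over the list alone, adjusted p = 0.00094, adjusted p = 0.631 with an estimated correlation) and ribosomal genes for 3 of 29 (1 adjusted over the list alone, adjusted p = 0.000866, adjusted p = 0.633 with an estimated correlation). Of 15 p53 targets and cell cycle inhibitors 9 were higher and 1 lower (10 and 2 adjusted over the list alone, adjusted p = 0.00227, adjusted p = 0.631 with an estimated correlation), with the cell death genes Bax and Bbc3 5.57- and 17.4-fold higher. Inflammation genes were higher for 4 of 15 and lower for 1 (5 and 1 adjusted over the list alone, adjusted p = 0.0252, adjusted p = 0.659 with an estimated correlation). Of 29 cell cycle genes 2 were lower (0 adjusted over the list alone, adjusted p = 0.00945, adjusted p = 0.712 with an estimated correlation). The summed CPM of the inflammation list was 2492, 4625 and 303 in iCEC 1, 2 and 3 and 106, 134 and 286 in pCEC 1, 2 and 3, so that iCEC 3 lay near pCEC 3. That of the cell cycle list was 1038, 1297 and 357 in iCEC and 1164, 1663 and 1382 in pCEC, so that iCEC 2 lay within the pCEC range. The inflammation call was lost without iCEC 1 (adjusted p = 0.0699) or iCEC 2 (0.103), and the cell cycle call without iCEC 3 (0.453).

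Of 16278 genes tested between iCEC and pCEC, edgeR called 3327, of which 1713 were higher and 1614 lower in iCEC, and camera called 12 of 31 lists. Genes at 0 in every pCEC library included the transcription factors Tbx3 and Hoxb9, at least 273- and 264-fold higher in iCEC. The gene count was 1353, 1131 and 1138 without pCEC 1, pCEC 2 and pCEC 3. Among the 125 called genes eligible to be named, 61 lost the threshold without at least 1 library. With pCEC represented by the library labelled polyA RNA alone, edgeR called 0 genes, with 2529 at an unadjusted p under 0.05 and a lowest adjusted p of 0.078, so that none of the gene calls between iCEC and pCEC given here passed. Their direction was the same there, and over all alternatives the log2 fold change ran from -10.81 to -9.68 for Col8a2 and from 5.88 to 7.19 for Acta2, but from -10.89 to -7.47 for Col1a2 and from -11.99 to -9.63 for Lum. The gene lists were not tested in that setting. Transcripts without a polyA tail summed to 187 and 161 CPM in pCEC 2 and pCEC 3, labelled total RNA, within the 111 to 346 CPM of the 7 libraries labelled polyA RNA, so these levels did not separate the labels.

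**Figure D3:**
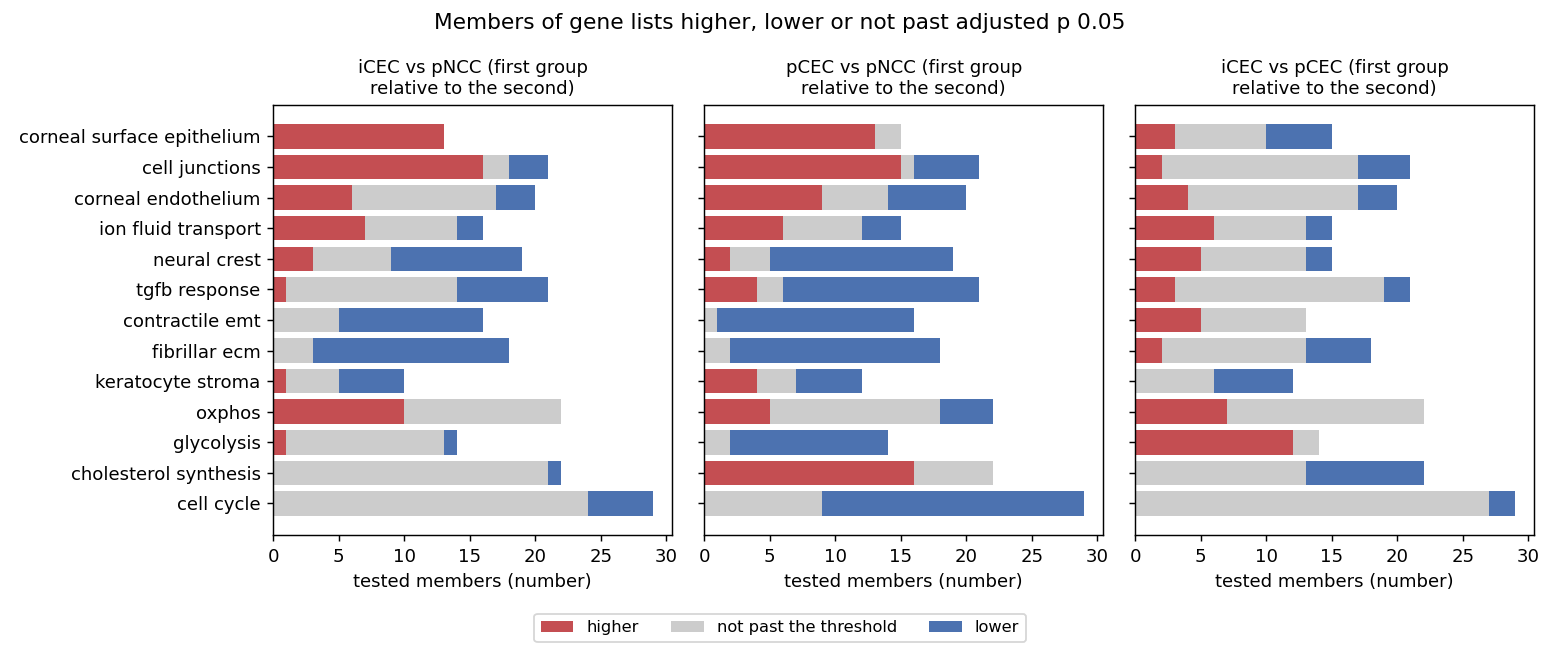
Number of tested members of 13 gene lists that were higher, lower or not past adjusted p 0.05 in the first group of each comparison relative to the second; each bar spans the tested members of a list. All 13 tested surface epithelium genes were higher in iCEC than in pNCC, and 12 of 14 glycolysis genes were higher in iCEC than in pCEC.

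The changes of iCEC and of pCEC against pNCC largely shared their direction. Of 15647 genes tested in both comparisons, 3947 were called in both with the same direction, of which 1879 were higher and 2068 lower. Independent lists would give 667 and 841, which takes no account of the shared pNCC libraries. Krt5, Esrp1, Trp63 and Foxc1 were higher in both, and Prrx1, Zeb1 and Acta2 lower in both. Among the 3947 genes, 812 (20.6%) also differed between iCEC and pCEC. In opposite directions 206 genes were called, of which 126 were higher in iCEC and lower in pCEC. A further 5487 genes called in pCEC vs pNCC were not called in iCEC vs pNCC. Across genes, which are not independent replicates, the log2 fold changes had a Pearson r of 0.756 and a covariance of 5.86. With no group difference, the shared pNCC libraries alone gave a mean r of 0.507, a covariance of 0.167 and 0 genes called in both by edgeR in 20 simulated sets. A count near 0 follows from simulating no difference, so it does not show what 2 unlike groups that both differ from pNCC would share. A split that kept the pNCC libraries together and mixed iCEC with pCEC gave 2998 genes in the same direction. Without pNCC 1, pNCC 2 and pNCC 3, the count of 3947 became 2091, 1939 and 2226.

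Sex-linked transcripts differed between libraries of a group. Xist, the RNA of the inactive X chromosome, and 4 summed genes of the Y chromosome were each compared with their pNCC mean. Both reached 5% or more of it in all 3 pNCC libraries and in pCEC 2 and pCEC 3. In iCEC 1 and iCEC 3 Xist stood at 942 and 1437 CPM and the Y sum at 1.74 and 0.0498 CPM, and in iCEC 2 Xist stood at 0.172 CPM and the Y sum at 202 CPM. In pCEC 1 Xist stood at 2.25 CPM and the Y sum at 280 CPM.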

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

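The comparison of iCEC with pCEC was planned, and its use for the genes of this part followed from their opposite changes against pNCC. In opposite directions against the same 3 pNCC libraries, 206 genes changed in iCEC and in pCEC, and all 206 were also called by edgeR between iCEC and pCEC. Since the genes were selected for opposite changes in the same libraries, a difference between iCEC and pCEC was nearly fixed by the selection, and the adjusted p values below add little evidence. These counts say how the groups differ and not why, and no explanation was tested. No gene passed between iCEC and pCEC when pCEC was represented by the library labelled polyA RNA alone (0 genes called by edgeR, 2529 at an unadjusted p under 0.05). Over all alternatives the log2 fold change of iCEC minus pCEC ran from -10.81 to -9.68 for Col8a2, -10.99 to -8.73 for Aqp1, -4.36 to -2.24 for Fmod, -3.76 to -3.21 for Insig1, 1.77 to 2.19 for Cox7c, 1.58 to 2.38 for Hk1 and 8.47 to 9.52 for Pitx1. DESeq2 and the gene lists were not run in that setting.

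Among the 206 genes, 7 were members of the gene lists, and in each the 3 iCEC libraries all lay on one side of the 3 pCEC libraries. The log2 fold change of iCEC minus pCEC was -9.84 for the water channel Aqp1 (adjusted p = 0.00245 by edgeR) and -10.36 for the Descemet's membrane collagen Col8a2 (adjusted p = 0.00286). It was 1.91 for the respiratory chain subunit Cox7c (adjusted p = 0.00688), 1.80 for the hexokinase Hk1 (adjusted p = 0.00735) and 8.97 for the transcription factor Pitx1 (adjusted p = 0.00513). It was -3.45 for the sterol sensor Insig1 (adjusted p = 0.00252) and -3.78 for the proteoglycan Fmod (adjusted p = 0.0187), the latter lost without iCEC 1 (adjusted p = 0.0601), pCEC 2 (0.0629) or pCEC 3 (0.0631). Without iCEC 1 the value was -10.99 for Aqp1 and -9.69 for Col8a2, and without pCEC 2 it was -9.68 for Col8a2 and -3.16 for Fmod. Col8a2 kept its calls in iCEC vs pNCC and in pCEC vs pNCC without any 1 library, and Pitx1 its call in iCEC vs pNCC. The calls of Pitx1, Cox7c, Hk1 and Insig1 in pCEC vs pNCC were not recomputed.

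Calls against pNCC were less firm for 5 of the 7 genes. Cox7c lost its call in iCEC vs pNCC without pNCC 1 (adjusted p = 0.0644), pNCC 2 (0.0579) or pNCC 3 (0.0623), and Hk1 without pNCC 1 (adjusted p = 0.101), pNCC 2 (0.109) or pNCC 3 (0.0751). Insig1 lost it without pNCC 1 (adjusted p = 0.0617), pNCC 2 (0.0568), pNCC 3 (0.074), iCEC 1 (0.0772), iCEC 2 (0.0825) or iCEC 3 (0.0545). Fmod lost it without pNCC 1 (adjusted p = 0.111), pNCC 2 (0.0629), pNCC 3 (0.0978), iCEC 1 (0.0861) or iCEC 2 (0.0503). In pCEC vs pNCC, Fmod lost its call without pNCC 2 (adjusted p = 0.091), pNCC 3 (0.054), pCEC 2 (0.0768) or pCEC 3 (0.0557), and Aqp1 without pNCC 2 (adjusted p = 0.0818), pNCC 3 (0.0602), pCEC 2 (0.11) or pCEC 3 (0.101). Both also lost it with the polyA-labelled pCEC library alone, with no filter and with the replicate block, and Aqp1 with all 9 libraries in 1 fit. Their log2 fold changes fell as low as 0.23 for Fmod and 0.39 for Aqp1, so the calls of these 2 genes in opposite directions depended on the setting, although no sign changed.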

How the results depend on the processing

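A filter of 1 CPM in every library was the only setting here chosen after the data were seen. It left 2842 genes called in iCEC vs pNCC, 6722 in pCEC vs pNCC and 1962 in iCEC vs pCEC, since it removes genes that fell near 0 in a group and so tests fewer genes (10720, 10958 and 10866). With replicate number as a block, 2864 genes were called in iCEC vs pNCC, 1295 in iCEC vs pCEC and 2384 in both comparisons against pNCC. The numbers did not pair the libraries (iCEC 1 and pNCC 1 had r = -0.0519), and the cause was not tested beyond that. With pCEC represented by the library labelled polyA RNA alone, iCEC vs pCEC gave 0 genes by edgeR (2529 at an unadjusted p under 0.05), with 1 pCEC library that is assumed to vary like the iCEC libraries. With 1 library left out, calls ran from 2322 to 7684 in iCEC vs pNCC, 1131 to 4974 in iCEC vs pCEC and 1939 to 5351 in both comparisons against pNCC, and the lowest values came without a pNCC or pCEC library. Camera with an estimated correlation called 1 list in iCEC vs pNCC, 0 in pCEC vs pNCC and 0 in iCEC vs pCEC, against 14, 10 and 12 with the preset correlation, and fry called 16, 18 and 12. The distance ratio was 0.789 with the 2000 most variable genes and 0.703 with 1 minus Spearman correlation, and the cause was not tested. DESeq2, size factors, no filter, a filter of 1 CPM in 3 libraries, 1 fit of all 9 libraries and a minimum of 2-fold kept every gene count within 1.5 times. Of 5877 values of named genes under the planned settings 5186 kept direction and threshold, 691 no longer passed and 0 reversed. The pseudocount setting was not run, since the data are counts.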

Other observations

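The tests of where the epithelial transcripts in pCEC and iCEC came from, and that of short mitochondrial mRNAs, were chosen after the results were seen. The tests of other splits were chosen before. That of nuclear copies was chosen before its own result, but for mitochondrial mRNAs already picked by their low level in these libraries. Signalling and basement membrane genes went both ways. The laminin chains Lama5, Lama3 and Lamb3 of epithelial basement membranes were 80.5-, 21.8- and 41.1-fold higher in iCEC than in pNCC, and Lama2, a laminin of muscle and mesenchyme, was 1271-fold lower. Of 20 basement membrane genes 6 were higher and 8 lower (6 and 9 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.336, downward, with fry upward). In pCEC, Lama5 was 52.2-fold higher than in pNCC and Lama4 946-fold lower. Retinoic acid genes were higher for 6 of 10 members in iCEC and lower for 1, also adjusted over the list alone (camera adjusted p = 0.0693). The retinal dehydrogenase Aldh1a1 was 211-fold higher in iCEC and 228-fold higher in pCEC than in pNCC. Without iCEC 1 the log2 fold change in iCEC was 7.07 for Aldh1a1 (7.75 with all libraries) and -9.61 for Lama2 (-10.26), without iCEC 3 it was -10.98 for Lama2, and without pCEC 2 that of Lama4 in pCEC was -10.86 (-9.88).

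Targets of the Wnt pathway did not move together. In iCEC relative to pNCC 5 of 11 members were higher and 3 lower, also adjusted over the list alone (camera adjusted p = 0.69), with the Wnt inhibitor Rnf43 76.9-fold higher, at a log2 fold change of 6.27 that was 7.18 without pNCC 2. The list summed to 460, 429 and 3114 CPM in iCEC 1, 2 and 3, so that iCEC 3 stood apart. In pNCC 1, 2 and 3 it summed to 337, 353 and 260 CPM. In pCEC relative to pNCC 3 of 10 were higher and 4 lower (camera adjusted p = 0.849), with the stem cell receptor Lgr5 1036-fold lower. Its log2 fold change of -9.98 was -10.79 without pCEC 1 and -9.33 without pCEC 2. Of 13 BMP targets 3 were higher in iCEC than in pNCC and 1 lower (camera adjusted p = 0.85), and the inhibitor of differentiation Id2 was 10.2-fold higher in iCEC and 12.8-fold in pCEC. The BMP antagonist Grem1 was at 0 in every pCEC library and at least 6763-fold lower there than in pNCC. The periocular factor Eya2 was 508-fold higher in iCEC and 201-fold higher in pCEC than in pNCC.

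Surface epithelium transcripts were high in the libraries labelled pCEC. A swap of a pCEC library with one of another group found no partner, since the highest Krt12 level in iCEC and pNCC was 0.000224% of the pCEC mean. Surface epithelial cells in the pCEC samples and corneal endothelial cells that carry these transcripts themselves cannot be told apart. That 13 of 15 members of the surface epithelium list were higher in pCEC than in pNCC, with Krt5 at 29934 CPM and Krt12 at 11095 CPM, restates the pattern and favours neither. The ratio of Col8a2 to Krt12 differed 4.346 times among the 3 libraries, which lies between the bounds set, and Kera, of the stroma, differed 9.32 times.

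Surface epithelium transcripts in iCEC also had more than 1 candidate source. Outgrowth of epithelial cells present in the pNCC cultures is 1 candidate. In pNCC, 12 of 13 members stood within a factor of 3 of a median of 0.410% of their iCEC level. The exception was Krt15 at 0.0055%. This test was chosen after the results were seen, and a similar share does not show where those transcripts came from. Growth of each iCEC library from few founder cells or 1 embryo stays open. At 5% or more of the pNCC mean, 0 of 3 iCEC libraries held both Xist and Y-linked transcripts, against 3 of 3 in pNCC and 2 of 3 in pCEC. Below that limit, iCEC 1 still held Y-linked transcripts at 1.74 CPM, 1.51% of the pNCC mean. The pattern was seen before the test was chosen and so does not support such growth. A response of the neural crest cells to SB431542 cannot be told apart from these, since treatment and group coincide: 7 of 21 TGF-β response genes were lower in iCEC than in pNCC, and 15 were lower in pCEC, which the labels give no inhibitor.

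Of 13 mitochondrial mRNAs 6 (mt-Nd3, mt-Nd4l, mt-Co2, mt-Co3, mt-Atp6 and mt-Atp8) had means from 0.4495 to 6.48 CPM over the 9 libraries, and the other 7 from 369.4 to 9560 CPM. For mt-Co2, mt-Co3 and mt-Atp6, shortness was argued against by mt-Nd6. With 519 bases it is shorter than these and stood 56.99 times above the highest of the 6. It is longer than mt-Nd3, mt-Nd4l and mt-Atp8 (348, 297 and 204 bases), so for them the comparison cannot decide. Reads shared with nuclear copies of the mitochondrial genome may have been left uncounted, as 5 of the 6 had 90% or more of their sequence windows of 100 bases in another annotated transcript and 6 of the other 7 under 50%. The exceptions were mt-Atp8 with 0% and mt-Nd4 with 60.75%. Only annotated transcripts were searched, so a share of 0% does not exclude a copy outside the annotation. The low level of mt-Atp8 stays unexplained, with shortness left open, and no biological explanation was tested.

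Other splits of the libraries were tested for each comparison. With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. In each comparison 1 split, the real one, reached the real count of 5093, 10382 and 3327 genes, and the highest of the others was 0 genes by edgeR (at most 538, 136 and 538 genes at an unadjusted p under 0.05), and DESeq2 was not run on the splits. For lists called by camera, 4 splits reached the real 14 in iCEC vs pNCC (highest other 18), 5 reached the real 10 in pCEC vs pNCC (highest other 15) and 1 reached the real 12 in iCEC vs pCEC (highest other 10). The number of lists called thus does not set the real groups apart from mixed ones in iCEC vs pNCC and in pCEC vs pNCC. For genes changed in both comparisons against pNCC, 1 of 40 drawn splits of the 9 libraries, the real one, reached 3947, a share under 0.05. The highest other, 2998, kept the 3 pNCC libraries together and mixed the other groups, and most others broke up pNCC and gave 0 genes by edgeR. The test thus speaks to a difference from pNCC and not to chance agreement between iCEC and pCEC.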
